A study of Zea mays with 48 samples.

How the data were processed

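The series holds 48 libraries of maize line B73 from 4 tissues and 4 temperature conditions with 3 replicates each. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a QuantSeq 3′ mRNA-Seq kit (forward version), which reads a short stretch near the 3′ end of polyadenylated transcripts, and were sequenced on an Illumina NextSeq. Read counts therefore do not scale with transcript length. The submitters' processing notes name STAR, an aligner, and edgeR, with no versions. The genome build, the counting step and its strand setting, and any use of molecular identifiers are not given in the sources used here. Genes that overlap, or that have near-identical copies, can share reads and are uncertain for that reason, as are genes with an antisense partner.

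The authors deposited raw counts per gene for each library, as whole numbers over 46430 identifiers, and these counts were the input of every test. The authors also deposited 1 table per tissue of values called CPM. Each of its columns was the matching raw count times 1 constant, with a relative deviation of at most 5e-10, and the constants correspond to effective library sizes, so column totals differ between libraries. The implied factors ran from 0.765 to 1.43 and differed by at most 3.93% from the TMM factors computed here. These tables held 18385 (leaf), 19828 (top crown), 20829 (bottom crown) and 21187 (root) genes, among them all genes tested here, and were used only for this check.

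Of the identifiers, 44146 were nuclear gene models, 1765 were ENSRNA features, 154 were microRNA loci, 208 were mitochondrial and 157 plastid. The name table, of assembly Zm-B73-REFERENCE-NAM-5.0, matched 0 nuclear gene models and 0 ENSRNA features, 153 microRNA loci and all organelle genes. No coordinates are given, because the build of the files is not known. The gene lists fixed before the data were examined could therefore not be filled: across 37 lists the names matched psaJ among tested light-harvesting and photosystem genes and the mitochondrial genes rps12, rps1, rps2B and rps7 in the list of cytosolic ribosomal proteins, to which they do not belong. No list reached the 5 tested members needed, so list tests and sums of tissue markers were not run. In their place, groups were defined from the data after they were seen. Organ-enriched genes had at least 10 CPM in 1 organ and 8 times the level of the other organs, in the libraries of the 2 chilling conditions not under comparison. In another tissue only members passing its low-count filter were tested. A member low in control can pass through chilled libraries alone, which can add to rises there. Response groups were genes called and changed at least 2-fold in another organ, whose libraries are separate. Mitochondrial genes and ENSRNA features formed the remaining groups.

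Total counts per library ran from 3449880 to 8633854. Replicates of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom of at least 4.01, so no library was treated as a copy of another. A gene with no counts in all 3 libraries of a group was given a bound at a floor of 3 counts per library, and bounds cover counting error only. Placing such genes at their bound changed no group median by more than 0.158.

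Each tissue was fitted on its own 12 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr over the 4 conditions, TMM factors, robust quasi-likelihood fits of 4 condition means, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors are those implied by the quasi-likelihood F value. There were 12 comparisons with control and 12 direct comparisons between chilling conditions. Comparisons of a tissue share control libraries, so chilling conditions were compared directly and not by overlap of their calls. The crown parts were compared in 1 fit of 24 libraries, with the interaction of crown part and chilling. Leaf and root calls were overlapped only between fits without shared libraries, beside the number that independent lists would share. Whether samples of different tissues with the same number came from the same plants is not stated, so independence between tissues is assumed. Because biological repeats are not described further, p-values measure the spread between these samples.

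Gene groups were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 132 tests of groups in comparisons with control. Of these, 70 passed with the preset correlation and 25 with an estimated one, all 25 among the 70. The fry test, which asks whether a group's genes move on balance one way, passed 78.

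Genes were named by a rule written before the data were examined: adjusted p under 0.05, at least 10 CPM in a compared group, no overlap of the 3 libraries per group, the largest changes, and a name. For identifiers without names at most 2 risen and 2 fallen per comparison were taken. The condition on overlap was not applied to crown interactions, which compare more than a pair of groups. Organelle genes below 10 CPM given in the text were chosen after their values were seen.

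Alternatives written before the data were examined were DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate number as a block, a fit of only the 6 libraries compared, a fit of all 48 libraries, and leaving out each library. Library size without a scaling factor was added after seeing the data, as were all alternatives of the group tests. Groups share replicate numbers, so it was checked whether libraries with the same number deviate together. In 4 of 24 comparisons every such correlation was above 0.1: whole-plant against root-only chilling in bottom crown, and in root root-only chilling against control, whole-plant against shoot-only and whole-plant against root-only chilling. Over all comparisons the correlations ran from -0.301 to 0.401. The pairing in those 4 comes from this check of the data and not from the labels. With the block their counts were 4478, 1952, 10341 and 3478, within 1.5 times the counts without it.

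The code was tested on simulated data. Counts for root-only chilling against control in leaf were simulated from control leaf means, with only chosen genes changed (14265 genes tested). There edgeR recovered 50% of 100 genes changed 2-fold and 92% of 100 changed 4-fold, with 13 false calls. The real comparison called 7456 genes, with TMM factors of 1.22 to 1.45 under root-only chilling. The simulation therefore does not test scaling under such a shift. DESeq2 recovered 50% and 91%, with 19 false calls.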

Results

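RNA was measured in maize seedlings of the inbred line B73 at the stage of 3 leaves, in 48 libraries from 4 tissues: leaf, top crown, bottom crown and root. The crown is the junction of shoot and root, and the labels do not define its top and bottom parts further. Each tissue was taken from control plants, with shoot and root at 26 °C, and from plants chilled for 24 h in 1 of 3 ways. In whole-plant chilling shoot and root were at 4 °C, in shoot-only chilling the shoot was at 4 °C and the root at 26 °C, and in root-only chilling the shoot stayed at 26 °C while the root was at 0 °C. The labels do not say at which of the 2 temperatures the crown parts were held under local chilling. Because the root was at 4 °C in one chilled-root condition and at 0 °C in the other, whole-plant and root-only chilling differ in root temperature as well as in the shoot. Each of the 16 groups had 3 libraries, called biological repeats in the series' design text. Whether each came from 1 plant or a pool is not stated. Total counts per library ran from 3449880 (leaf, control replicate 2) to 8633854 (bottom crown, whole-plant chilling replicate 1). Levels below are CPM (counts scaled to a common library total) on TMM-scaled library sizes, given as mean ± SD with n = 3, and changes are log2 fold changes with a standard error (SE) from edgeR's quasi-likelihood test.

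The design asks how each tissue responds when it is itself chilled and when only a distant part of the plant is. The deposited identifiers of nuclear genes could not be paired with names, so nuclear genes are described by groups measured in these data and by a few identifiers. Organelle genes have names. These libraries were primed on poly(A) tails, which most plant mitochondrial and plastid transcripts lack in stable form, so organelle values describe the captured part of those RNAs. Nuclear copies of organelle DNA can share their reads, which makes organelle levels uncertain.

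**Figure D1:**
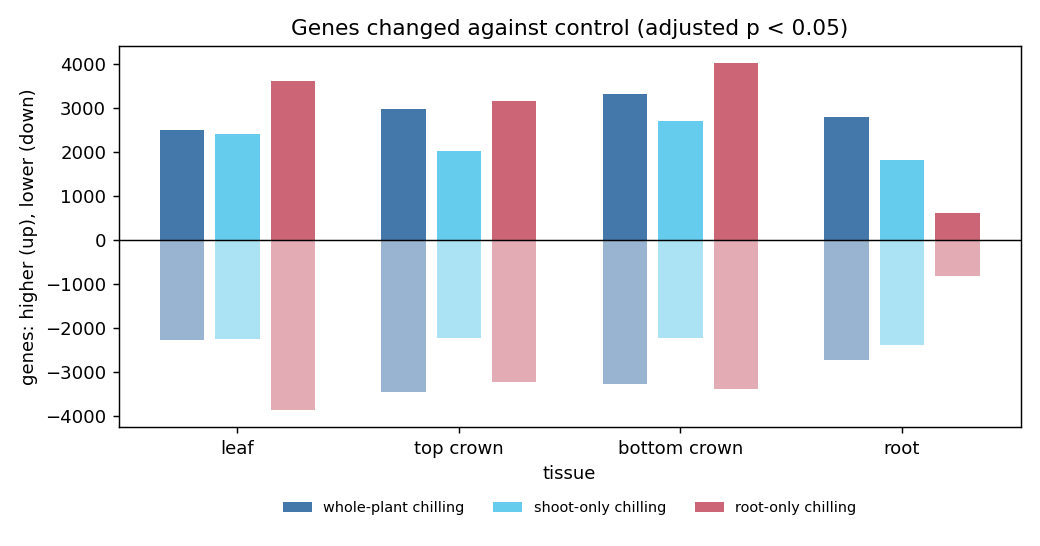
Genes changed against control in each tissue (x axis), as number of genes higher (bars upward) and lower (bars downward, paler) at an adjusted p below 0.05 in edgeR, coloured by chilling condition. The leaf has its highest count under root-only chilling (7456 genes) and the root its lowest under the same condition (1435 genes).

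In leaf, whole-plant chilling raised 2505 genes and lowered 2264 of 15845 tested, and shoot-only chilling raised 2408 and lowered 2250. Zm00001d044426 had no counts in any control library and reached 106.7 ± 33.3 CPM under whole-plant chilling, at least 149-fold above the floor of 3 counts per library, and 97.6 ± 18.4 CPM under shoot-only chilling, at least 136-fold. Zm00001d041960 went from no counts in control to 68.5 ± 27.1 CPM and 54.6 ± 17.4 CPM. Among the genes that fell, Zm00001d006285 was at 0.243 ± 0.254 CPM under whole-plant chilling against 10.3 ± 4.73 CPM in control. Zm00001d043047 was at 6.60 ± 4.44 CPM under shoot-only chilling against 217.8 ± 12.6 CPM. Of 118 tested ENSRNA features, the annotation's non-coding RNA entries, 91 rose and none fell under whole-plant chilling (median 1.93), and 84 rose and 1 fell under shoot-only chilling (median 1.80). The camera test set both groups apart from the other genes (adjusted p = 1.7e-28 and 3.3e-26), and both calls held with an estimated correlation (adjusted p = 0.019 and 0.018). Values of ENSRNA features, in all tissues, describe only the part captured by poly(A) priming, and changes in tailing were not measured.

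Organelle genes changed in the chilled leaf too. The mitochondrial 5S ribosomal RNA gene rrn5 (ZeamMr003) rose from 11.7 ± 4.08 CPM in control to 38.3 ± 6.85 CPM under whole-plant chilling (1.73, SE 0.30, adjusted p = 0.00025) and to 42.5 ± 13.3 CPM under shoot-only chilling (1.88, SE 0.30, adjusted p = 0.00012). The cytochrome c oxidase subunit gene cox1 (ZeamMp136) rose under whole-plant chilling (2.49, SE 0.74, adjusted p = 0.025), a call that ended without control replicate 3 (adjusted p = 0.075), whole-plant replicate 1 (0.080) or whole-plant replicate 3 (0.073). The small ribosomal RNA gene rrn18 (ZeamMr004) rose under whole-plant chilling from 25.2 ± 18.5 to 65.5 ± 4.88 CPM (1.41, SE 0.44, adjusted p = 0.031). That call ended without control replicate 3 (adjusted p = 0.089), without whole-plant replicates 1 (0.081), 2 (0.073) or 3 (0.078), with only the 6 libraries compared (0.051), with library size alone (0.074) and with the replicate number as a block (0.064). In all, 6 of 20 tested mitochondrial genes rose under whole-plant chilling and 3 of 20 under shoot-only chilling. As a group they had a median of 0.93 under whole-plant chilling (camera adjusted p = 0.02; adjusted p = 0.58 with an estimated correlation), and that call ended without control replicate 1 (median 0.58) or whole-plant replicate 1 (0.84). Of 7 plastid genes tested, psaJ (ZemaCp043), a photosystem I subunit, fell under whole-plant chilling (-1.12, SE 0.38, adjusted p = 0.028) and under shoot-only chilling (-1.95, SE 0.41, adjusted p = 0.001). It was the 1 tested member of the light-harvesting and photosystem list fixed in advance. The plastid maturase gene matK (ZemaCp003) rose under whole-plant chilling from 39.6 ± 6.82 to 73.9 ± 6.72 CPM (0.90, SE 0.26, adjusted p = 0.015). This call ended without control replicate 1 (0.78, adjusted p = 0.069) and with library size alone in place of TMM (0.70, adjusted p = 0.089).

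Root-enriched genes, markers of another organ defined from these data, also moved in the cold leaf. Only members passing the low-count filter in leaf were tested, 100 for shoot-only and 143 for whole-plant chilling, against 358 and 452 in root. The shoot-only group was low in control leaf, at a mean log2 CPM of 1.17 to 1.33. Members can pass that filter through chilled libraries alone, which can add to the share that rose. Under shoot-only chilling 45 of 100 rose and 9 fell (median 0.81, camera adjusted p = 1.1e-05; adjusted p = 0.032 with an estimated correlation). Under whole-plant chilling 40 of 143 rose and 22 fell (median 0.39, camera adjusted p = 0.028; adjusted p = 0.24 with an estimated correlation), a call that ended without control replicate 1 (median 0.30) or whole-plant replicate 2 (0.41).

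Scaled by library size alone, the median of all genes moved by -0.21 for whole-plant and -0.16 for shoot-only chilling of the leaf, and the split became 1852 higher against 3274 lower and 1862 against 2988. The direct comparison of these conditions, in which the leaf was equally cold and the root was at 4 or 26 °C, found 11 of 15845 genes, 9 higher and 2 lower under whole-plant chilling. Zm00001d017545 was at 18.4 ± 5.31 CPM under whole-plant chilling and 2.94 ± 1.84 CPM under shoot-only chilling, and Zm00001d020708 was at 30.5 ± 5.38 against 133.4 ± 68.0 CPM. The count was 1 without whole-plant replicate 2, and 2, 4 and 6 without shoot-only replicates 1, 2 and 3. It was 21 in DESeq2 and 96 without the low-count filter. With only the 6 libraries compared it was 0 in edgeR, with 508 genes at an unadjusted p under 0.05 and 28 in DESeq2, and Zm00001d017545 and Zm00001d020708 then had an adjusted p of 0.053 and 0.076. Each also lost its call without single libraries: Zm00001d017545 without whole-plant replicate 2 (adjusted p = 0.066) or shoot-only replicates 1 (0.078) and 3 (0.089), and Zm00001d020708 without whole-plant replicate 2 (0.073).

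In leaf under root-only chilling, where the leaf itself stayed at 26 °C, 3600 genes rose and 3856 fell of 15845 tested. Leaf-enriched genes, defined in the libraries of the other 2 chilling conditions as those of at least 10 CPM in leaf and at least 8 times the level of every other organ, fell together: 569 of 685 fell and 28 rose, with a median of -1.43. Their mean log2 CPM was between 5.75 and 5.95 in the 3 root-only libraries and between 7.26 and 7.33 in the 3 control libraries. The camera test gave an adjusted p = 1.8e-52, and the call held with an estimated correlation (adjusted p = 0.0065). Zm00001d050577 had no counts in control leaf and 109.6 ± 19.5 CPM under root-only chilling, at least 153-fold higher, and Zm00001d014083 rose from 0.0683 ± 0.118 to 448.2 ± 86.9 CPM. Zm00001d026436 and Zm00001d016947 fell from 26.5 ± 12.8 and 10.9 ± 2.30 CPM to no counts, at least 67.8-fold and at least 27.8-fold lower. Root-enriched genes that passed the low-count filter in leaf moved with this condition as well, with the same limit. Of these, 55 of 155 rose and 27 fell in leaf (median 0.46, camera adjusted p = 0.0041, and 0.14 with an estimated correlation), a call that ended with library size alone (median 0.89). Of the ENSRNA features 37 fell and 1 rose (median -0.79, camera adjusted p = 0.01), a call lost with an estimated correlation (adjusted p = 0.42).

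The leaf-enriched genes of the conditions with a cold leaf were defined the same way from the remaining libraries. These include the other cold-leaf condition, from which the leaf differed in only 11 of 15845 genes. Genes lowered by cold of the leaf tend to be left out of such a group, so its median is partly set by the definition. The root-only group was defined from whole-plant and shoot-only chilling, both with a cold leaf. Neither had a warm leaf above a chilled root, but whole-plant chilling shares the chilled root. Under whole-plant chilling 71 of 694 rose and 134 fell (median 0.00, camera adjusted p = 0.19), and under shoot-only chilling 82 of 699 rose and 150 fell (median -0.04, camera adjusted p = 0.066). The shoot-only group passed the camera test without shoot-only replicate 3 (median -0.08) and with library size alone (-0.20). Each condition has its own gene group, and the difference between the groups was not tested. Under root-only chilling rrn5 rose from 11.7 ± 4.08 to 20.9 ± 6.63 CPM (0.85, SE 0.30, adjusted p = 0.027), a call that ended without control replicate 1 (adjusted p = 0.15) or root-only replicate 3 (0.13) and with all 48 libraries in 1 fit (0.07). matK fell from 39.6 ± 6.82 to 21.3 ± 9.16 CPM (-0.88, SE 0.27, adjusted p = 0.012), and trnK (ZemaCt121), whose intron holds matK so that they can share reads, and which was chosen after its values were seen, fell from 155.2 ± 108.6 to 50.9 ± 22.9 CPM (-1.60, SE 0.59, adjusted p = 0.049). The call of matK ended without control replicate 2 (-0.74, adjusted p = 0.061) and with library size alone (-0.43, adjusted p = 0.24). All genes moved by a median of 0.42 with library size alone, and 6487 genes were then higher and 2568 lower.

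**Figure D2:**
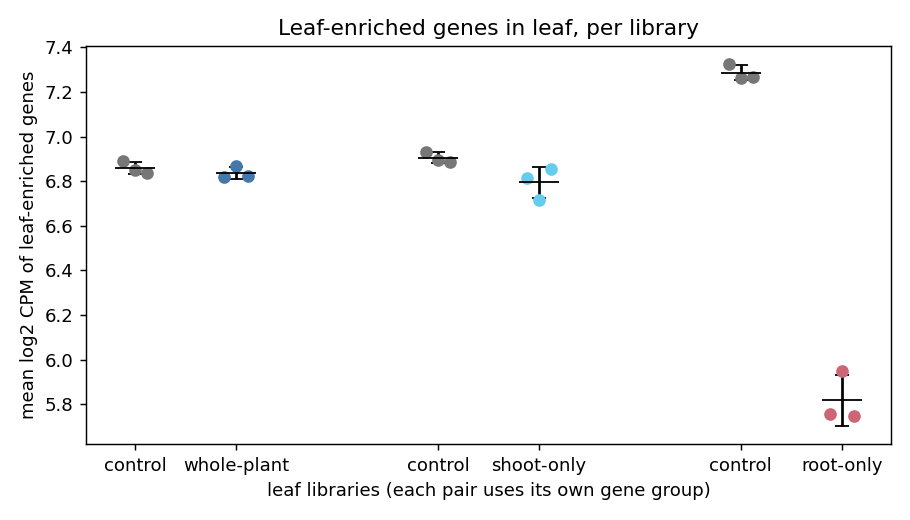
Mean log2 CPM of leaf-enriched genes (y axis, not starting at 0) in each leaf library (points), with the mean and SD of 3 libraries (lines), for control and each chilling condition. Each pair of columns has its own gene group, and the 3 root-only libraries sit between 5.75 and 5.95, below their controls at 7.26 to 7.33.

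Set directly against each other, leaf under whole-plant and root-only chilling differed in 9185 genes (4765 higher and 4420 lower under whole-plant chilling), and shoot-only and root-only chilling in 9247 (4691 higher and 4556 lower under shoot-only chilling). Zm00001d037779 was at 1012 ± 478.3 CPM under whole-plant chilling and 797.2 ± 144.2 CPM under shoot-only chilling, against 0.338 ± 0.109 CPM under root-only chilling. Zm00001d014083 went the other way, at 0.155 ± 0.269 CPM under whole-plant and 448.2 ± 86.9 CPM under root-only chilling. Among organelle genes matK was higher under whole-plant than root-only chilling (1.78, SE 0.27, adjusted p = 2.1e-05) and higher under shoot-only than root-only chilling (1.40, SE 0.27, adjusted p = 0.00025). cox1 was higher under whole-plant (3.01, SE 0.70, adjusted p = 0.0033) and shoot-only chilling (2.50, SE 0.72, adjusted p = 0.011) than under root-only chilling, the latter with an adjusted p = 0.05 without shoot-only replicate 1. trnK was higher under whole-plant chilling (2.08, SE 0.59, adjusted p = 0.013) and rrn5 under shoot-only chilling (1.03, SE 0.27, adjusted p = 0.0037), calls that ended with library size alone (adjusted p = 0.059 and 0.13). That scaling moved the median of all genes by -0.63 and -0.58 in these comparisons, and the splits became 2889 higher against 8210 lower and 2981 against 7985.

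In root, whole-plant chilling raised 2800 and lowered 2715 of 18831 genes tested, and root-only chilling raised 625 and lowered 810. Mitochondrial genes rose in both: 9 of 24 rose and none fell in each, with a median of 0.91 under whole-plant chilling and 1.27 under root-only chilling. The gene of ribosomal protein rps7 (ZeamMp159) rose from 13.1 ± 3.95 CPM in control to 49.4 ± 12.2 CPM under whole-plant chilling (1.91, SE 0.28, adjusted p = 0.00013) and to 91.5 ± 6.19 CPM under root-only chilling (2.80, SE 0.28, adjusted p = 2.4e-05). The ribosomal RNA gene rrn5 rose from 53.9 ± 11.98 CPM to 309.8 ± 161.7 CPM (2.52, SE 0.37, adjusted p = 0.00013) and 270.5 ± 61.1 CPM (2.33, SE 0.37, adjusted p = 0.00089). The ribosomal protein gene rps12 (ZeamMp092) rose from 12.4 ± 3.21 CPM to 40.2 ± 10.7 CPM and 36.5 ± 6.58 CPM. cox1 rose from 9.92 ± 4.80 CPM to 29.9 ± 9.68 CPM and 32.9 ± 4.13 CPM, the latter a call that ended without control replicate 3 (1.57, adjusted p = 0.061). rrn18 rose from 168.6 ± 54.8 to 526.5 ± 207.5 CPM under whole-plant (1.64, SE 0.35, adjusted p = 0.0025) and 433.3 ± 56.5 CPM under root-only chilling (1.36, SE 0.35, adjusted p = 0.025). The root-only call of rrn18 ended without control replicates 1 (adjusted p = 0.12) or 3 (0.11) or root-only replicates 1 (0.08) or 3 (0.083). The large ribosomal RNA gene rrn26 (ZeamMr002) rose under whole-plant chilling from 738.3 ± 279.3 to 1473 ± 270.3 CPM (adjusted p = 0.035). Its call ended without control replicates 1 (0.13) or 3 (0.098) or whole-plant replicates 1 (0.075) or 2 (0.068), with only the 6 libraries compared (0.075) and with library size alone (0.17). As a group the mitochondrial genes passed the camera test in both conditions (adjusted p = 0.0027 and 2.2e-13), and both calls were lost with an estimated correlation (adjusted p = 0.57 and 0.15). ENSRNA features also rose, 102 of 193 with 1 fallen under whole-plant chilling (median 1.40) and 76 of 193 with none fallen under root-only chilling (median 1.22). The latter call held with an estimated correlation (adjusted p = 0.04) and the former did not (adjusted p = 0.2). Root whole-plant replicate 1 stood apart from the other 2: its chi-square per degree of freedom against them was 39.3 and 33.0, against 14.4 between them, with 21358 genes detected against 23317 and 23332 and an ENSRNA share of 0.762% against 0.584% and 0.482%. Its mean log2 CPM of root-enriched genes was 4.16, against 4.53 and 4.67. Without it the whole-plant count was 5477 and the medians were 1.10 for ENSRNA features, 0.76 for mitochondrial genes and -0.47 for root-enriched genes, with each camera call kept.

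Zm00001d043663 had no counts in control root and 79.3 ± 44.9 CPM under whole-plant chilling, at least 162-fold higher, and 13.1 ± 2.94 CPM under root-only chilling, at least 26.8-fold higher. Zm00001d021772 fell from 16.9 ± 6.99 CPM in control to no counts under whole-plant chilling, at least 21.4-fold lower, and to 0.0474 ± 0.0821 CPM under root-only chilling. Root-enriched genes, defined for each condition from the libraries of the other 2 in the way of the leaf-enriched ones, fell in every condition. The whole-plant and root-only groups each draw on libraries of the other condition with a cold root. Genes lowered by root cold tend to be left out of them. Their medians are thus partly set by the definition and cannot be ranked against that of shoot-only chilling. Under whole-plant chilling 175 of 452 fell and 61 rose (median -0.50), under shoot-only chilling 131 of 358 fell and 20 rose (median -0.81), and under root-only chilling 142 of 435 fell and 32 rose (median -0.42). The camera adjusted p was 9.6e-09, 3.9e-12 and 1.2e-17. With an estimated correlation the shoot-only and root-only calls held (adjusted p = 0.0043 and 0.032) and the whole-plant call was lost (adjusted p = 0.14). Crown-enriched genes, markers of the adjoining tissue, rose in root under whole-plant chilling among the members that passed the low-count filter there (18 of 74, with 3 fallen, median 0.58, camera adjusted p = 0.044, and 0.65 with an estimated correlation). That call ended without control replicates 2 (median 0.45) or 3 (0.44) or whole-plant replicate 1 (0.41), with RLE size factors (0.62) and in the fry test (adjusted p = 0.08). The root-only count of 1435 changed genes was 852 without control replicate 3, 890 without root-only replicate 1 and 914 without root-only replicate 2, and 2516 with all 48 libraries in 1 fit. The whole-plant count of 5515 was 3666 with only the 6 libraries compared. The whole-plant split under library size alone became 1829 higher against 4630 lower, all genes moving by -0.32.

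Shoot-only chilling, under which the root stayed at 26 °C, raised 1814 genes in root and lowered 2382. Zm00001d036542 rose from 0.918 ± 1.17 to 219.6 ± 125.7 CPM, and Zm00001d031811 rose from no counts to 12.4 ± 7.35 CPM, at least 25.4-fold. Zm00001d012394 fell from 11.5 ± 1.87 to 0.361 ± 0.173 CPM. None of the 24 tested mitochondrial genes passed the test in edgeR or in DESeq2, and 1 had an unadjusted p under 0.05. Of the 193 ENSRNA features 1 rose and 10 fell (median -0.35, camera adjusted p = 0.094), a group that passed without shoot-only replicate 2 (median -0.48). The count of 4196 changed genes was 2466 without control replicate 1 and 2633 without shoot-only replicate 3, and 6348 with all 48 libraries in 1 fit. Its split under library size alone became 1125 higher against 3116 lower, all genes moving by -0.17.

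Direct comparisons in root found 9639 genes between whole-plant and shoot-only chilling (5043 higher and 4596 lower under whole-plant chilling), 7073 between shoot-only and root-only chilling (3255 higher and 3818 lower under shoot-only chilling) and 2640 between whole-plant and root-only chilling (1671 higher and 969 lower under whole-plant chilling). rps7 was higher under whole-plant than shoot-only chilling (2.03, SE 0.28, adjusted p = 3.9e-05), as was rrn5 (2.42, SE 0.37, adjusted p = 8.3e-05). rps7 was lower under whole-plant than under root-only chilling (-0.89, SE 0.26, adjusted p = 0.035), a comparison in which the root was at 4 °C against 0 °C as well. This call ended without whole-plant replicates 2 (adjusted p = 0.058) or 3 (0.13) or root-only replicates 1 (0.097), 2 (0.075) or 3 (0.1). Against root-only chilling, shoot-only chilling had lower rps7 (-2.92, SE 0.29, adjusted p = 3.2e-06), rrn5 (-2.23, SE 0.37, adjusted p = 0.00027) and cox1 (-2.08, SE 0.38, adjusted p = 0.0006). Zm00001d007049 was at 1051 ± 532.1 CPM under shoot-only chilling and at 0.0770 ± 0.133 CPM under whole-plant and 0.0517 ± 0.0895 CPM under root-only chilling. Zm00001d043062 had no counts under shoot-only chilling and 136.7 ± 26.1 CPM under whole-plant chilling, at least 253-fold higher. The count between whole-plant and root-only chilling was 1665 without root-only replicate 2, 1605 with only the 6 libraries compared, 4509 with all 48 libraries in 1 fit and 4335 with library size alone, which turned the split to 1033 higher against 3302 lower (all genes moving by -0.40). The split between shoot-only and root-only chilling became 2133 against 5002 (all genes moving by -0.25).

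**Figure D3:**
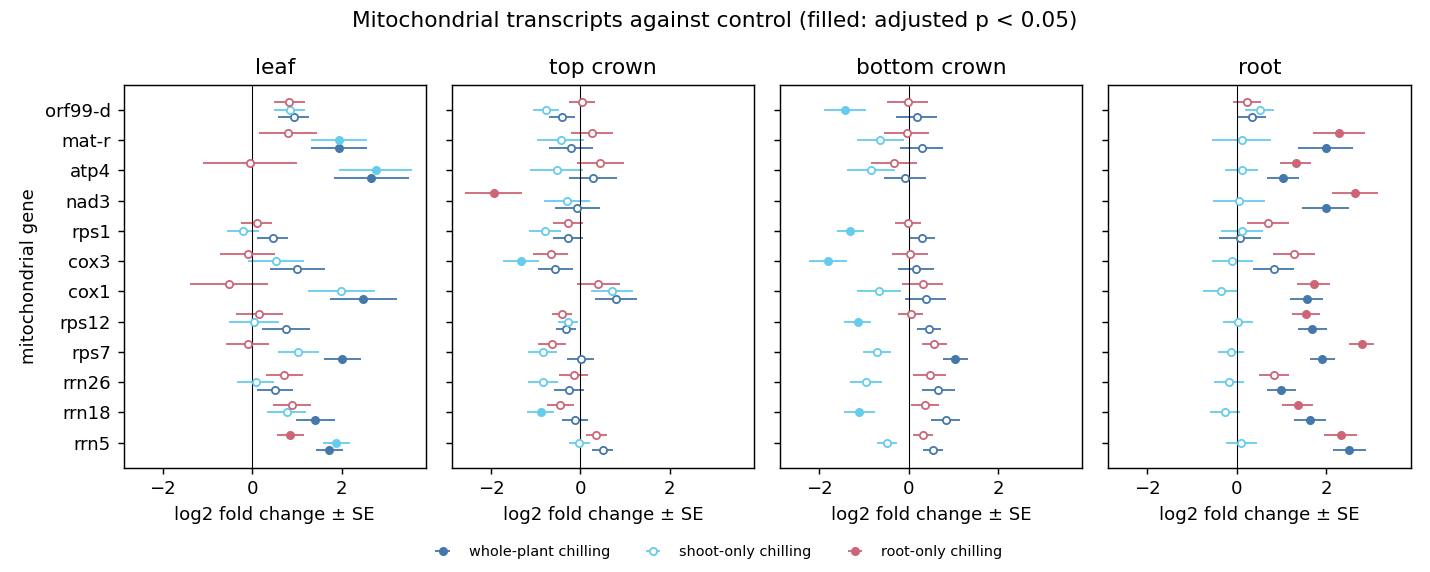
Log2 fold change against control (x axis, with SE) of the named mitochondrial genes (y axis) in each tissue, for whole-plant, shoot-only and root-only chilling; filled points have an adjusted p below 0.05 in edgeR. In root, rps7 lies at 1.91 and 2.80 under the conditions with a cold root, and in bottom crown cox3 lies at -1.80 under shoot-only chilling.

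In top crown, whole-plant chilling raised 2967 and lowered 3447 of 17706 genes, shoot-only chilling raised 2024 and lowered 2211, and root-only chilling raised 3151 and lowered 3211. Zm00001d044426, one of the genes that rose most in chilled leaf, rose from 0.0578 ± 0.1001 to 63.5 ± 23.6 CPM under whole-plant chilling. Zm00001d011183 rose from 0.222 ± 0.193 to 39.4 ± 11.3 CPM under shoot-only chilling, and Zm00001d010529 fell from 37.6 ± 9.98 to 2.06 ± 0.250 CPM. Under root-only chilling Zm00001d018206 fell from 25.2 ± 1.19 to 1.79 ± 0.914 CPM. ENSRNA features rose under whole-plant (51 of 98 rose, 7 fell, median 1.18), shoot-only (45 rose, 4 fell, median 1.26) and root-only chilling (37 rose, 6 fell, median 0.77), with camera adjusted p of 5.7e-13, 9.9e-13 and 0.0011. These calls were lost with an estimated correlation (adjusted p = 0.065, 0.065 and 0.37). Under shoot-only chilling 4 of 20 mitochondrial genes fell and none rose. The group had a median of -0.67 (camera adjusted p = 0.0096; adjusted p = 0.58 with an estimated correlation), and its call ended without control replicate 2 (median -0.51) and in the fry test (adjusted p = 0.11). cox3 (ZeamMp161), a cytochrome c oxidase subunit gene, fell from 62.0 ± 22.6 to 24.7 ± 2.25 CPM (-1.33, SE 0.41, adjusted p = 0.037). Its call ended without control replicates 2 (adjusted p = 0.12) or 3 (0.086) or shoot-only replicates 1 (0.097), 2 (0.086) or 3 (0.085), and with all 48 libraries in 1 fit (0.1). The open reading frame orf101-a (ZeamMp044) fell under whole-plant (-0.69, SE 0.25, adjusted p = 0.036) and shoot-only chilling (-0.71, SE 0.25, adjusted p = 0.043). Its whole-plant call ended in DESeq2 (adjusted p = 0.055), in the fit of all 48 libraries (0.2) and without control replicates 1 (0.068) or 2 (0.14) or whole-plant replicates 1 (0.077), 2 (0.11) or 3 (0.075). Its shoot-only call ended in DESeq2 (0.061), with RLE size factors (0.051), in the fit of all 48 libraries (0.22) and without control replicates 1 (0.08) or 2 (0.15) or shoot-only replicates 1 (0.097), 2 (0.11) or 3 (0.093). The plastid ATP synthase gene atpF (ZemaCp019), chosen after its values were seen, fell from 3.13 ± 1.94 CPM to 0.404 ± 0.327 CPM under shoot-only and 0.454 ± 0.119 CPM under root-only chilling.

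The count for shoot-only chilling in top crown was 2689 without shoot-only replicate 3. Root-only replicate 3 lay further from the others than they from each other (chi-square per degree of freedom 13.5 and 7.54, against 4.76), and without it the root-only count was 5710 and the ENSRNA median 0.81. Under library size alone the splits became 1535 higher against 5467 lower under whole-plant chilling (all genes moving by -0.25) and 1400 against 2865 under shoot-only chilling (-0.11). Direct comparisons in top crown found 4576 genes between whole-plant and shoot-only chilling (2217 higher and 2359 lower under whole-plant chilling), 4766 between whole-plant and root-only chilling (2198 higher and 2568 lower under whole-plant chilling) and 4110 between shoot-only and root-only chilling (1934 higher and 2176 lower under shoot-only chilling). Zm00001d010667 was at 66.5 ± 1.14 CPM under whole-plant chilling against 0.260 ± 0.451 CPM under shoot-only and 2.14 ± 1.01 CPM under root-only chilling. Zm00001d007411 was at 87.7 ± 27.8 CPM under root-only chilling against 0.275 ± 0.240 CPM under whole-plant and 0.0651 ± 0.113 CPM under shoot-only chilling. Without shoot-only replicate 3 the counts against shoot-only chilling were 3047 and 2702. Under library size alone the splits became 1407 against 3207 between whole-plant and shoot-only chilling (all genes moving by -0.14) and 1189 against 3465 between whole-plant and root-only chilling (-0.16).

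In bottom crown, whole-plant chilling raised 3310 and lowered 3267 of 18779 genes, shoot-only chilling raised 2695 and lowered 2217, and root-only chilling raised 4011 and lowered 3382. Zm00001d041960, which also rose in chilled leaf, had no counts in control and 27.4 ± 4.57 CPM under whole-plant chilling, at least 60.7-fold higher. Zm00001d011183 rose under shoot-only chilling here too, from 1.12 ± 0.971 to 183.2 ± 17.6 CPM. Zm00001d007411 rose under root-only chilling from 0.0482 ± 0.0835 to 25.2 ± 10.3 CPM. Zm00001d032115 fell from 11.8 ± 1.61 CPM to 0.154 ± 0.0330 CPM under whole-plant and 0.0610 ± 0.106 CPM under root-only chilling. Mitochondrial genes fell under shoot-only chilling, 7 of 19 with none rising. cox3 (ZeamMp161) fell from 86.5 ± 4.75 to 24.6 ± 7.29 CPM (-1.80, SE 0.43, adjusted p = 0.012), and the ribosomal protein gene rps1 (ZeamMp097) from 200.3 ± 17.5 to 81.2 ± 17.9 CPM (-1.30, SE 0.30, adjusted p = 0.0076). Calls that ended in some fits were those of rps12 (-1.14, SE 0.30, adjusted p = 0.012; 0.053 without control replicate 2, 0.052 without shoot-only replicate 3), orf101-a (-1.23, SE 0.33, adjusted p = 0.013; 0.061 without control replicate 1, 0.057 without shoot-only replicate 3) and the transfer RNA gene trnR-a (ZeamMt017; -1.04, SE 0.30, adjusted p = 0.019; 0.059 and 0.086 without those libraries). The call of orf99-d (ZeamMp050; -1.42, SE 0.47, adjusted p = 0.048) ended without control replicates 1 (0.14) or 3 (0.092) or shoot-only replicates 1 (0.14) or 3 (0.14), without the low-count filter (0.094), with only the 6 libraries compared (0.073) and with library size alone (0.055). That of rrn18 (-1.10, SE 0.34, adjusted p = 0.032) ended without control replicates 1 (0.078), 2 (0.084) or 3 (0.06) or shoot-only replicates 1 (0.11), 2 (0.055) or 3 (0.1), and without the low-count filter (0.076). The group had a median of -0.84 (camera adjusted p = 2.8e-05; adjusted p = 0.37 with an estimated correlation). Under whole-plant chilling 1 of 19 mitochondrial genes passed in edgeR and 2 in DESeq2. The gene passing in edgeR was rps7, rising from 6.71 ± 0.557 to 13.8 ± 2.09 CPM (1.04, SE 0.28, adjusted p = 0.0081). Under root-only chilling none of these 19 passed in edgeR or DESeq2, nor had any an unadjusted p under 0.05 in edgeR.

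Root-enriched genes that passed the low-count filter in bottom crown rose there under root-only chilling, 101 of 274 with 27 fallen (median 0.73, camera adjusted p = 0.0011, and 0.22 with an estimated correlation). Crown-enriched genes rose under shoot-only chilling, under which leaf-enriched and mitochondrial genes fell (19 of 53 rose, 3 fell, median 0.42, camera adjusted p = 0.00082; adjusted p = 0.32 with an estimated correlation). Leaf-enriched genes fell in bottom crown under root-only chilling (152 of 520, with 39 risen, median -0.41, camera adjusted p = 0.00026; adjusted p = 0.53 with an estimated correlation) and shoot-only chilling (120 of 515, with 30 risen, median -0.34, camera adjusted p = 7.8e-05; adjusted p = 0.53 with an estimated correlation and 0.073 in the fry test). ENSRNA features rose under whole-plant (73 of 121, with 6 fallen, median 1.66), shoot-only (41 of 121, with 6 fallen, median 0.69) and root-only chilling (61 of 121, with 7 fallen, median 1.26). The camera calls of ENSRNA features were lost with an estimated correlation (adjusted p = 0.062, 0.24 and 0.2). Under shoot-only chilling their share of all counts was not higher: 0.0902% ± 0.0153 against 0.0997% ± 0.00816 in control, with overlapping libraries. Bottom crown whole-plant replicate 1 stood apart from the other 2 (chi-square per degree of freedom 19.9 and 23.0, against 8.37 between them), and without it the whole-plant count was 6046. So did shoot-only replicate 2 (14.2 and 12.01, against 4.69), with a mitochondrial share of 0.153% against 0.0750% and 0.0654% and a TMM factor of 1.11 against 0.956 and 0.948. Without it the shoot-only count was 4841 and the medians were -0.89 for mitochondrial, -0.38 for leaf-enriched and 0.33 for crown-enriched genes, with each camera call kept. The count for shoot-only chilling was 3262 without control replicate 3. Under library size alone the splits became 1762 higher against 4851 lower under whole-plant (all genes moving by -0.23), 1611 against 3008 under shoot-only (-0.16) and 2572 against 5749 under root-only chilling (-0.27).

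Direct comparisons in bottom crown found 7435 genes between whole-plant and shoot-only chilling (3586 higher and 3849 lower under whole-plant chilling), 4459 between whole-plant and root-only chilling (1748 higher and 2711 lower under whole-plant chilling) and 6406 between shoot-only and root-only chilling (2981 higher and 3425 lower under shoot-only chilling). cox3 was higher under whole-plant than shoot-only chilling (1.96, SE 0.43, adjusted p = 0.0049), as were rrn18 (1.93, SE 0.34, adjusted p = 0.00096), and rps7 (1.74, SE 0.30, adjusted p = 0.00028). Zm00001d008223 was at 58.5 ± 22.7 CPM under whole-plant against 0.0589 ± 0.102 CPM under shoot-only chilling. Shoot-only chilling had lower cox3 (-1.85, SE 0.43, adjusted p = 0.0081), rrn18 (-1.47, SE 0.34, adjusted p = 0.0059) and ccmFN (ZeamMp098), a cytochrome c maturation gene (-1.63, SE 0.44, adjusted p = 0.016), than root-only chilling. The call of ccmFN ended without shoot-only replicates 2 (adjusted p = 0.051) or 3 (0.063) or root-only replicate 2 (0.054). Under library size alone the split between shoot-only and root-only chilling became 3672 higher against 2617 lower (all genes moving by 0.11).

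The crown parts differed in 10120 of 19595 genes in control plants, 4844 higher in top crown and 5276 higher in bottom crown. The difference between their responses, tested as an interaction, passed for 152 genes under whole-plant chilling (61 with the more positive response in top crown, 91 in bottom crown), 19 under shoot-only chilling (4 and 15) and 586 under root-only chilling (220 and 366). Zm00001d004744 was at 24.9 ± 8.85 CPM in top crown and 2.77 ± 1.23 CPM in bottom crown under whole-plant chilling, against 4.79 and 14.9 CPM in the controls, a difference in response of 4.78 (SE 0.44, adjusted p = 1.1e-06). Zm00001d044705 was at 49.3 ± 12.3 and 16.3 ± 4.41 CPM under shoot-only chilling, against 19.7 and 88.1 CPM in the controls (3.75, SE 0.35, adjusted p = 2.7e-06). Zm00001d028230 was at 3.15 ± 0.707 and 54.6 ± 16.9 CPM under root-only chilling, against 5.58 and 7.01 CPM in the controls (-3.76, SE 0.52, adjusted p = 0.00022).

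The interaction counts depended on the fit and on single libraries. DESeq2 gave 322 for whole-plant and 104 for shoot-only chilling, and all 48 libraries in 1 fit gave 66, 5 and 351 for whole-plant, shoot-only and root-only chilling. The shoot-only count was 65 without the low-count filter and 36 with the replicate number as a block. The whole-plant count fell to 57, 97 and 62 without bottom crown control replicates 1, 2 and 3, to 81 without top crown control replicate 3, to 82 and 68 without top crown whole-plant replicates 1 and 3, and to 92 without bottom crown whole-plant replicate 2. The shoot-only count was 1 without any one of top crown control replicate 2, bottom crown control replicate 3 and top crown shoot-only replicates 2 and 3. It was 2 without bottom crown control replicate 1, 12 without top crown control replicate 3, 10 without bottom crown shoot-only replicate 3 and 35 without top crown shoot-only replicate 1. The root-only count was 330 without top crown control replicate 2, 376 without bottom crown control replicate 3 and 389 without bottom crown root-only replicate 2. With library size alone the root-only split turned to 433 against 250 (all genes moving by 0.14), and with RLE size factors the shoot-only split became 5 against 11.

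Leaf and root were compared through fits that share no libraries. Of 14581 genes tested in both, 309 rose in both the chilled leaf (shoot-only chilling) and the chilled root (root-only chilling), where independent lists would share 75.02, and 181 fell in both, against 71.03. In the organs that were not themselves chilled, leaf under root-only and root under shoot-only chilling, 392 genes rose in both against 350.9 for independent lists, and 650 fell in both against 389.3. The shared counts for chilled organs were 198 risen and 118 fallen without root control replicate 3, 204 and 119 without root root-only replicate 1, 100 fallen without root root-only replicate 2 and 117 fallen without root root-only replicate 3. Those for unchilled organs were 221 risen and 408 fallen without root control replicate 1, 254 risen without root control replicate 2 and 421 fallen without root shoot-only replicate 3. With all 48 libraries in 1 fit 336 fell in both chilled organs, and 596 rose and 1081 fell in both unchilled organs.

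Genes that had risen at least 2-fold in root under root-only chilling were followed in the other tissues. In leaf 297 of 405 rose and 9 fell under whole-plant chilling (median 2.59), 286 rose and 9 fell under shoot-only chilling (median 2.40), and 75 rose and 107 fell under root-only chilling (median -0.11, camera adjusted p = 0.69). The leaf calls for whole-plant and shoot-only chilling held with an estimated correlation (adjusted p = 0.0014 for each). In bottom crown 335 of 462 rose under whole-plant chilling (median 1.66; adjusted p = 0.018 with an estimated correlation), 300 under root-only chilling (median 1.49; adjusted p = 0.054 with an estimated correlation) and 69 under shoot-only chilling, with 37 fallen (median 0.14, camera adjusted p = 0.24). In top crown 188 of 360 rose under whole-plant chilling (median 0.99; adjusted p = 0.013 with an estimated correlation), 158 under root-only chilling (median 0.76; adjusted p = 0.069 with an estimated correlation) and 56 under shoot-only chilling, with 49 fallen (median 0.03, camera adjusted p = 0.21). Differences between conditions in these group medians were not tested.

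Genes that had risen at least 2-fold in leaf under shoot-only chilling rose in root under whole-plant chilling (923 of 1561, median 1.23; adjusted p = 0.0014 with an estimated correlation) and under root-only chilling (291, with 82 fallen, median 0.27; adjusted p = 0.032 with an estimated correlation). Under shoot-only chilling 257 rose and 165 fell in root (median 0.12, camera adjusted p = 0.038; adjusted p = 0.34 with an estimated correlation), and the camera call ended without control replicate 1 (median 0.10), control replicate 3 (0.12) or shoot-only replicate 2 (0.07) and in the fry test (adjusted p = 0.054). In bottom crown 1008 of 1564 rose under whole-plant chilling (median 1; adjusted p = 0.013 with an estimated correlation), 1072 under root-only chilling (median 1.12; adjusted p = 0.015) and 398 under shoot-only chilling (median 0.29; adjusted p = 0.27 with an estimated correlation). In top crown the counts were 751, 667 and 321 of 1392, with medians of 0.71, 0.65 and 0.22 and an adjusted p of 0.013, 0.032 and 0.21 with an estimated correlation.

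**Figure D4:**
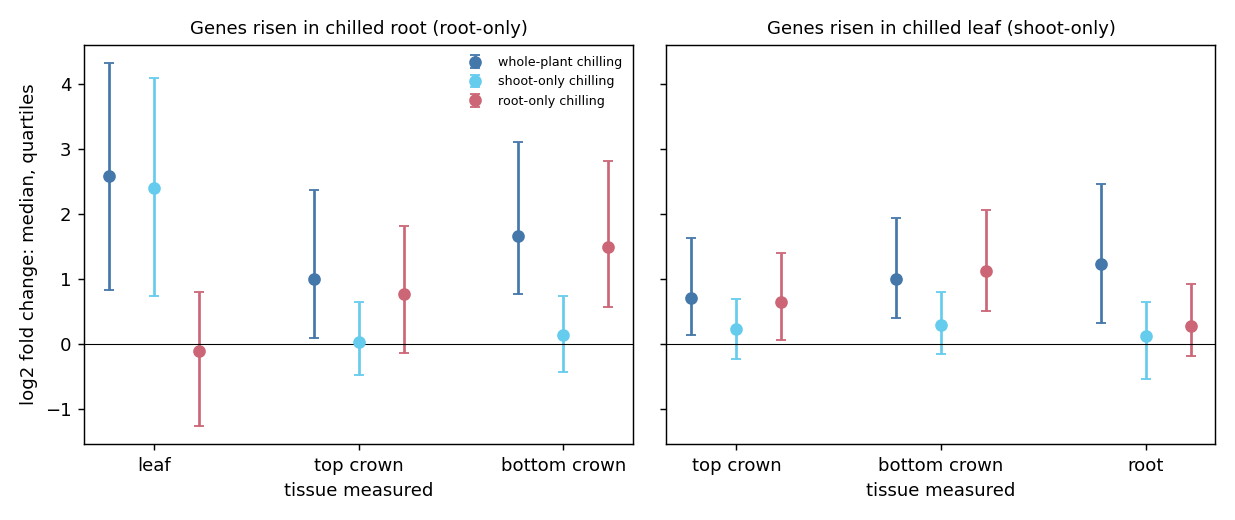
Median log2 fold change against control (points, with quartiles as bars) of genes risen at least 2-fold in root under root-only chilling (left) and in leaf under shoot-only chilling (right), in the tissues on the x axis and coloured by chilling condition. Genes risen in the chilled root have medians of 2.59 and 2.40 in the cold leaf and -0.11 in leaf under root-only chilling.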

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

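The tests of library scaling and of an equal mitochondrial rise were chosen after the results were seen. So was the sorting of the crown splits by side. The splits of libraries and the tests of non-leaf tissue and of depth were written before they were run. Those of non-leaf tissue and of depth concern a gene group that was itself defined after the data were seen.

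The difference between the responses of top and bottom crown was tested as an interaction and passed for 152 genes under whole-plant chilling, 19 under shoot-only chilling and 586 under root-only chilling. In 40 splits of the libraries, 4, 8 and 6 splits gave as many genes, the real one included, and the highest other counts were 3901, 7716 and 4671. These come from the structure of the samples: all of the 3, 7 and 5 other splits with as many genes turned most labels of chilled and control libraries in 1 crown part and not in the other, so that the responses add. They are no measure of chance for a difference in response. The other 22, 17 and 16 splits, on the same side in both parts, gave at most 49, 15 and 562 genes, but they mix chilled and control libraries within groups. Whether chance is excluded is left open for all 3 counts.

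The share of counts on ENSRNA features moved in opposite directions in different tissues, with every chilled library beyond every control library in each; the differences between tissues were not tested. Under shoot-only chilling it was higher in leaf (0.176% ± 0.00840 against 0.0619% ± 0.00794) and lower in root (0.243% ± 0.0464 against 0.353% ± 0.0426), a ratio of 4.12 between the treated-to-control ratios. Between top crown, also higher, and root that ratio was 2.28. Under root-only chilling the share was higher in root (0.767% ± 0.0559) and lower in leaf (0.0466% ± 0.00438), a ratio of 2.89. As a group of genes the features did not pass in root under shoot-only chilling (10 of 193 fell and 1 rose, camera adjusted p = 0.094). Their calls in leaf under root-only chilling and in top crown under shoot-only chilling were lost with an estimated correlation (adjusted p = 0.42 and 0.065), while those in leaf under shoot-only and root under root-only chilling held (adjusted p = 0.018 and 0.04). Whether these shifts reflect RNA level or capture by poly(A) priming was not tested.

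Leaf-enriched genes were lower in leaf under root-only chilling, with a median of -1.43. Library scaling moves all genes nearly alike. With library size alone the median of leaf-enriched genes was -1.01 and that of all genes 0.48, where TMM gave all genes 0.06. The group's own median thus stayed negative under both scalings. Its gap to the other genes could hardly change, because scaling shifts both alike, so the gap is no test of scaling. How much of the gap is a fall of these genes and how much a rise of others is not decided by this. Non-leaf tissue in the samples would need a share of 62.8% to give the fall, while crown-enriched transcripts reached 4.77% of their own organ's level in leaf (2.22% in control) and root-enriched ones 0.956% (0.675% in control). Depth is argued against: with every leaf library thinned to 3449880 counts the median was -1.45, and 6813 genes passed. A response of the leaf to the cold root, as the design names it, may then account for the fall; this is a hypothesis found and tested on the same libraries, and water status or other states of the leaf were not measured in them.

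Mitochondrial transcripts were higher in root under root-only chilling, with a median of 1.27. The tests of an equal rise of all mitochondrial RNA, as a loss of polyadenylated nuclear RNA could give, differ in what they decide. In the earlier one 4 features lay more than 2 SE from their weighted mean of 1.33, under its bound. By that bound an equal rise was not set aside. Staying under so wide a bound is not evidence for an equal rise either. The later one argues against an equal rise as the whole cause. There the 24 features spread about that mean by more than their SEs allow (chi-square 83.4 on 23 degrees of freedom, p = 8.8e-09, at most 0.00016 with any 1 feature left out). This p-value is approximate, since it takes the SEs as exact and the features as independent, while their estimated correlation was 0.523. An equal rise beside changes of single genes stays open, as do reads shared with nuclear copies, which can make an equal rise look unequal. Library scaling stays open too: library size alone gave a median of 1.33, but it moved all genes by only 0.08 and so decides nothing. Changes in tailing of these RNAs were not measured, and a response of the root to cold was not tested apart from them.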

How the results depend on the processing

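Chosen after seeing the data were library size alone, all alternatives of the group tests and the group tests set beside the overlaps. No named gene that passed its test reversed direction under any alternative run. No gene group that passed its test passed in the opposite direction under an alternative. The direction camera gives is relative to the other genes, which scaling shifts alike. It therefore does not show whether a small group median turned with the scaling. Counts were compared by size only, and their split into higher and lower genes did turn over with library size alone in some comparisons. In root whole-plant against root-only chilling it went from 63.3% to 23.8% higher, and in leaf root-only chilling against control from 48.3% to 71.6%. Further majorities turned with library size alone. Among them were leaf (52.5% to 36.1% higher) and root (50.8% to 28.3%) under whole-plant chilling against control. Bottom crown under root-only chilling against control went from 54.3% to 30.9%. The remaining splits kept their majority under that scaling. Genes fallen in leaf under root-only chilling, a group that did not pass in root under whole-plant chilling, went there from a median of 0.17 to -0.17 with library size alone. Without 1 library at a time, the calls of named genes held in 887 fits and ended in 115. Each count of changed genes stayed within 1.5 times its value in the report with RLE size factors. Elsewhere the exceptions were these, and their cause was not tested unless fewer or more libraries enter the fit. DESeq2 gave 21 genes for leaf whole-plant against shoot-only chilling, and 322 and 104 for the crown differences under whole-plant and shoot-only chilling. Without the low-count filter that leaf comparison gave 96 and the crown shoot-only difference 65. With only the 6 libraries compared, root whole-plant against control gave 3666 and root whole-plant against root-only 1605. The leaf whole-plant against shoot-only comparison then gave 0 in edgeR, with 508 of 13608 genes at an unadjusted p under 0.05 and 28 in DESeq2. With all 48 libraries in 1 fit, root gave 6348 for shoot-only and 2516 for root-only chilling against control and 4509 for whole-plant against root-only, the crown differences gave 66, 5 and 351, and the overlaps gave 336 fallen in chilled organs and 596 risen and 1081 fallen in unchilled organs. Library size alone gave 4335 for root whole-plant against root-only. With the replicate block the crown difference under shoot-only chilling gave 36, and the block moved no other count by over 1.5 times. It ended the call of rrn18 in leaf under whole-plant chilling and called leaf-enriched genes in bottom crown under whole-plant chilling, in comparisons whose libraries share only a number. Leaving out 1 library gave 1 to 15 for leaf whole-plant against shoot-only. In top crown it gave 2689 to 3618 for shoot-only against control, 3047 to 4321 for whole-plant against shoot-only and 2702 to 4014 for shoot-only against root-only. Bottom crown shoot-only against control had 3262 to 4841. In root the ranges were 2466 to 3825 for shoot-only, 852 to 1216 for root-only and 1665 to 2803 for whole-plant against root-only. Those of the crown differences were 57 to 181, 1 to 35 and 330 to 716, and those of the overlaps 198 to 304, 100 to 168, 221 to 360 and 408 to 618. Of 132 group tests, 45 lost their call with an estimated correlation.

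In the splits of 3 against 3 libraries the share cannot go below 0.1, so chance can be neither excluded nor upheld by it. The real split, 1 of 10, gave the highest count in each of the 24 comparisons within tissues and for the crown parts of control plants (10120), and the highest count of any other split was 2. For the overlaps 1 of 100 pairs of splits gave as many genes. The real counts were 309, 181, 392 and 650, and the highest others 16, 0, 0 and 0, where 16 is the real pair with direction turned (fallen in leaf, risen in root). Other splits of these leaf and root comparisons called 0 genes in edgeR, so they had none to share. These pairs therefore do not test whether the overlaps exceed those of independent lists. Each organ's response group tested in the other organ does, with an estimated correlation. Of genes risen in chilled organs both groups passed (adjusted p = 0.0014 in leaf and 0.032 in root), which argues against chance as long as control leaf and root samples, possibly of the same plants, vary independently. Chance is left open for genes fallen in chilled organs (adjusted p = 0.27 in leaf and 0.032 in root) and for those risen (0.75 and 0.8) and fallen (0.14 and 0.093) in unchilled organs. The tests of the fixed gene lists and their alternatives were not run, because the lists could not be filled. Depth limits organelle genes of a few CPM and genes absent from a group, for which only bounds are given.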

Other observations

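All groups and tests given here were chosen after the results were seen. Genes that had risen at least 2-fold in an organ that was not itself chilled were followed in the crown. Those risen in leaf under root-only chilling rose in top crown under the same condition (614 of 1999, with 287 fallen, median 0.14; adjusted p = 0.0043 with an estimated correlation). In bottom crown 689 of 2116 rose and 301 fell (median 0.15, camera adjusted p = 0.0011), a call lost with an estimated correlation (adjusted p = 0.055). The same group did not pass under whole-plant chilling (camera adjusted p = 0.54 in top crown and 0.59 in bottom crown) or shoot-only chilling (0.79 and 0.91), nor in root under any of the 3 conditions (0.73, 0.70 and 0.87). Those risen in root under shoot-only chilling rose under root-only chilling in top crown (247 of 784, with 101 fallen, median 0.20; adjusted p = 0.032 with an estimated correlation) and bottom crown (371 of 896, with 113 fallen, median 0.41; adjusted p = 0.04). Under whole-plant chilling their camera calls (adjusted p = 0.028 in top crown and 0.00051 in bottom crown) were lost with an estimated correlation (adjusted p = 0.14 and 0.12), and the call in top crown also ended without control replicate 1 (median 0.05) or whole-plant replicate 2 (0.03). Under shoot-only chilling, the condition that defined them, 103 rose and 104 fell in top crown (median 0.02, camera adjusted p = 0.85), and 147 rose and 95 fell in bottom crown (median 0.09, camera adjusted p = 0.59).

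Genes fallen at least 2-fold in leaf under shoot-only chilling fell in root under whole-plant chilling (490 of 1133, with 41 risen, median -0.77; adjusted p = 0.015 with an estimated correlation) and under root-only chilling (135, with 4 risen, median -0.31; adjusted p = 0.032 with an estimated correlation). Under whole-plant chilling they also fell in top crown (593 of 1134, median -0.73; adjusted p = 0.032 with an estimated correlation) and bottom crown (715 of 1214, median -0.81; adjusted p = 0.015 with an estimated correlation). Other calls of this group were lost with an estimated correlation: in top crown under shoot-only (median -0.35, adjusted p = 0.12) and root-only chilling (median -0.32, adjusted p = 0.28), and in bottom crown under shoot-only (median -0.28, adjusted p = 0.14) and root-only chilling (median -0.49, adjusted p = 0.069). In root under shoot-only chilling the group did not pass (median -0.12, camera adjusted p = 0.15). Genes with opposite calls were counted too. Risen in leaf under shoot-only and fallen in root under root-only chilling were 94, against 82.03 for independent lists, and fallen in leaf and risen in root were 16, against 64.95. For the unchilled organs, 389 rose in leaf under root-only and fell in root under shoot-only chilling, against 407.7, and 264 fell in leaf and rose in root, against 335. These opposite counts were not tested.

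Crown-enriched genes fell under root-only chilling in top crown (38 of 111, with 17 risen, median -0.21, camera adjusted p = 0.009; adjusted p = 0.42 with an estimated correlation) and bottom crown (38 of 111, with 21 risen, median -0.19, camera adjusted p = 0.028; adjusted p = 0.63 with an estimated correlation). The bottom crown call ended without control replicate 2 (median -0.14) or root-only replicates 2 (-0.07) or 3 (-0.13) and in the fry test (adjusted p = 0.1). With the rises in root under whole-plant chilling (camera adjusted p = 0.044) and in bottom crown under shoot-only chilling (0.00082), 4 of 12 tests of crown-enriched genes passed with the preset correlation. None of the 4 passed with an estimated correlation (adjusted p = 0.65 in root and 0.32 in bottom crown for these rises). In root under shoot-only chilling 8 of 28 were called lower and 1 higher, and the group did not pass (median -0.51, camera adjusted p = 0.066). It passed without control replicate 2 (median -0.72).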
